A study of Lactococcus cremoris with 2 samples.

How the data were processed

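Total RNA from *Lactococcus lactis* NIAI712, a lactic acid bacterium of milk fermentations, and from a variant cured of its plasmid pAG6, was measured on 1-colour NimbleGen arrays. A NimbleGen array carries oligonucleotide probes, several for each feature, where a feature is a predicted gene or open reading frame. RNA was purified with a commercial column kit and labelled with Cy3, with labelling done by the array's manufacturer, per the labels' protocols. There was 1 array per strain, so no difference has a replicate check and no p-value is given.

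Each array file gives, for 2533 features, an expression value, its standard error (SE) and the number of probes behind it, per the file headers. The values were made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays and combines the probes of a feature into 1 value. The version of RMA, the strain and genome build behind the probes and the growth conditions of the cultures are not given in the sources used here. The base of the logarithm is not stated either. It was taken as log2, RMA's usual scale, with which the highest deposited value of 15.19 is compatible for a 16-bit scanner. The number of probes was 36 for 2532 features and 32 for the remaining 1. The deposited SE of every feature was identical in the 2 arrays, so it is not an independent error of each array. It covers the disagreement among the probes of a feature and neither the culture, the RNA extraction nor the hybridisation. The series' table of log2 values, deposited by the authors, held the same numbers as the array files, with a largest difference of 0. No features marked as controls and no repeated feature IDs were found.

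The features are identified only by running numbers, which the files do not pair with gene names. None of the IDs (0 of 2533) matched a locus tag or accession in the gene table at hand, which describes the strain KW2, and no name was taken from position in that table. The 27 lists of pathway genes fixed before the data were examined could therefore not be evaluated. For the same reason only 2 feature IDs are printed on each side of the comparison. No feature is named for pAG6, so the loss of the plasmid could not be checked on a gene known to lie on it.

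The difference between strains was the log2 value of the cured variant minus that of the wild type, from the values as deposited, with no further scaling, filter or pseudocount. No SE is given for a ratio, since the deposited SEs of the 2 arrays are 1 shared number and not independent errors. Only as a yardstick for whether an alternative moved a feature's ratio, an interval was set from the root of their summed squares. Features were selected by size alone, as at least 2-fold higher or lower. The rule for named features, fixed before the data were examined, took the 12 highest and 12 lowest log2 ratios among features changed at least 2-fold whose mean log2 level was at or above the 25th percentile, after any feature of pAG6, with members of the gene lists and of runs to follow. Runs of at least 3 consecutive feature IDs all changed at least 2-fold in 1 direction were counted and set beside the counts over 1000 shuffles of the feature order. Whether ID order follows position in the genome is not stated. The 95% interval of the median log2 ratio came from 2000 bootstrap draws of features.

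Alternatives fixed beforehand were the medians of the arrays set equal, a second quantile normalization, removal of a loess curve of the ratio on mean level (lowess with a fraction of 0.3 and 3 iterations), a filter at the 25th percentile of mean level, a pseudocount at the 10th percentile of the linear values (14.2), the series' value table, thresholds of 1.5-fold and 3-fold, and run lengths of 2 and 4. The count at 8-fold was added after the values were seen. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data with 2533 features, of which 200 were changed 3-fold, with a noise SD of 0.18 on the log2 scale. The scripts recovered 100% of the changed features, called 0 unchanged ones and found the planted run of 12. With noise so far below the planted change, this outcome was nearly certain. Changes were planted at any level with no floor, so the test covers the scripts and not detection in the arrays. The number of arrays limits the precision of every value below.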

Results

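To compare gene expression with and without the plasmid pAG6, total RNA of wild-type *L. lactis* NIAI712 and of its pAG6-cured variant was hybridised to 1 array each. The plasmid is 8.7 kb long according to the labels. The variant coagulates milk slowly and the wild type normally, again according to the labels. Each array measured 2533 features, with a median log2 value of 5.86 and a range from 3.03 to 15.19 in the wild type. In the cured variant the median was 5.88 and the range ran from 3.01 to 15.09. The SE of a value, from the disagreement among its probes, had a median of 0.042 on the log2 scale and a highest value of 0.24. These errors do not include the variation between cultures, for which there were no replicates.

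The difference between the strains lay in a small set of features that were much lower in the cured variant. Of the 2533 features, 37 (1.46%) were at least 2-fold lower in the cured variant and 0 were at least 2-fold higher. The lower features had a median log2 value of 11.18 in the wild type and 6.85 in the cured variant, and their median difference was 16.2-fold. A total of 33 of them were at least 8-fold lower, with log2 ratios from -7.61 to -3.09. The other 4 had log2 ratios from -1.63 to -1.03, and no feature lay between -3.09 and -1.63. The deposited SE had a median of 0.075 over the 37 features and 0.042 over the others.

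**Figure D1:**
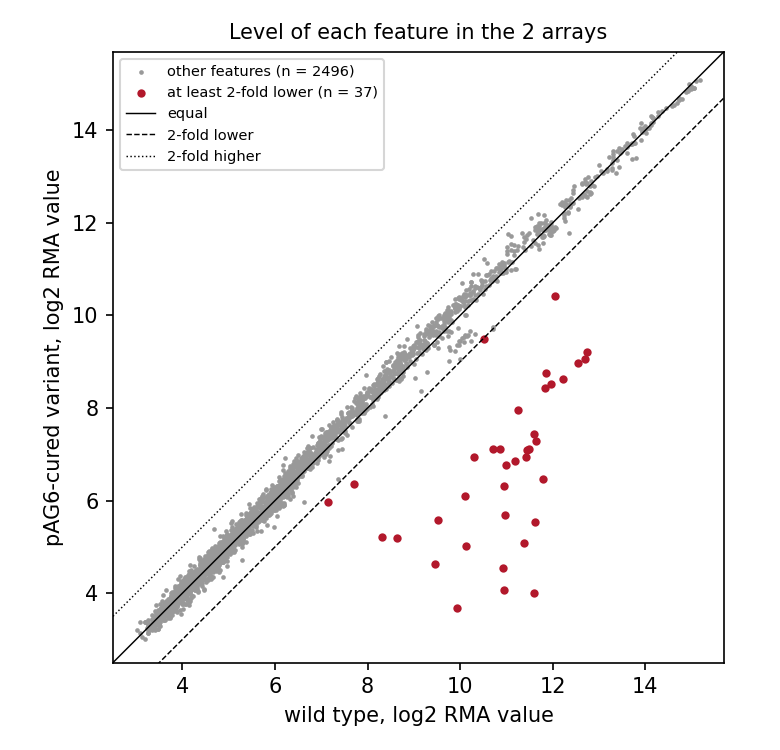
Log2 RMA value of each of the 2533 features in the cured variant (vertical axis) against the wild type (horizontal axis), 1 array per strain. Red points are the 37 features at least 2-fold lower in the cured variant, which had wild-type values from 7.15 to 12.73. No point lies above the dotted line of 2-fold higher values.

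The lowest ratio belonged to feature LLAC030500002013, whose log2 value was 11.60 in the wild type and 3.998 in the cured variant. Its log2 ratio was -7.61, and the deposited SE of its values was 0.136. The second lowest was LLAC030500000087, with 10.95 in the wild type, 4.06 in the cured variant and a log2 ratio of -6.89, with a deposited SE of 0.108. Both cured values were below the 25th percentile of that array, 4.49, where signal and background were not separated here, so no exact fold is given. With a pseudocount of 14.2 on the linear scale the log2 ratios of these features were -6.69 and -6.01. The remaining 10 of the 12 lowest had log2 ratios between -6.37 and -4.47, or between -5.81 and -4.20 with the pseudocount, and 1 of these 10 was also below the 25th percentile in the cured variant. At the other end, no feature met the rule for higher values. As deposited, the highest log2 ratios were 0.75 for LLAC030500001306 and 0.72 for LLAC030500001403, which correspond to 1.68-fold and 1.65-fold. Their order changed with the scaling: the log2 ratios were 0.68 and 0.76 after a second quantile normalization, and 0.52 and 0.59 after removal of the trend with level.

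All 37 lower features had been above the median of the array in the wild type. A feature near the bottom of the scale in the wild type had little room to be lower, so a gene lost with the plasmid but barely transcribed would not have been detected. In the cured variant the 37 features did not share 1 low level. Only 3 of them were at or below the 25th percentile of that array, 12 were at or below its median, and 9 remained above its 75th percentile. The lowest value was 3.67 and the highest 10.43.

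The lower features were grouped along the ID order. Of the 37, 27 lay in 5 runs of at least 3 consecutive IDs, whereas shuffled orders gave 0.006 such runs on average and at most 1 in 1000 shuffles. The longest run held 12 features, with a mean log2 ratio of -3.64 and an SD of 0.40 across those features, or 12.4-fold lower. Its log2 values went from a median of 11.84 in the wild type to 8.47 in the cured variant. Of the 5 runs, the lowest mean belonged to a run of 4 features with a mean log2 ratio of -6.33, a range from -7.61 to -5.32 and a median log2 value of 5.31 in the cured variant. It held 1 feature below the 25th percentile of the cured array, and its mean was -5.83 with the pseudocount, still the lowest of the 5. A run of 5 features averaged 11.2-fold lower, and its ratios ranged from -4.64 to -1.63. Both remaining runs held 3 features each and had mean log2 ratios of -4.78 and -2.99, the second of them with ratios from -4.38 to -1.03. The first of them also held 1 feature below that percentile, and its mean was -4.28 with the pseudocount. The remaining 10 lower features lay outside these runs. The first 127 IDs, a boundary set after the values were seen, held 26 of the 37 lower features, against 1.86 for an even spread. The other 101 IDs in that stretch were not 2-fold lower, though some fell just short, with log2 ratios down to -0.99.

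**Figure D2:**
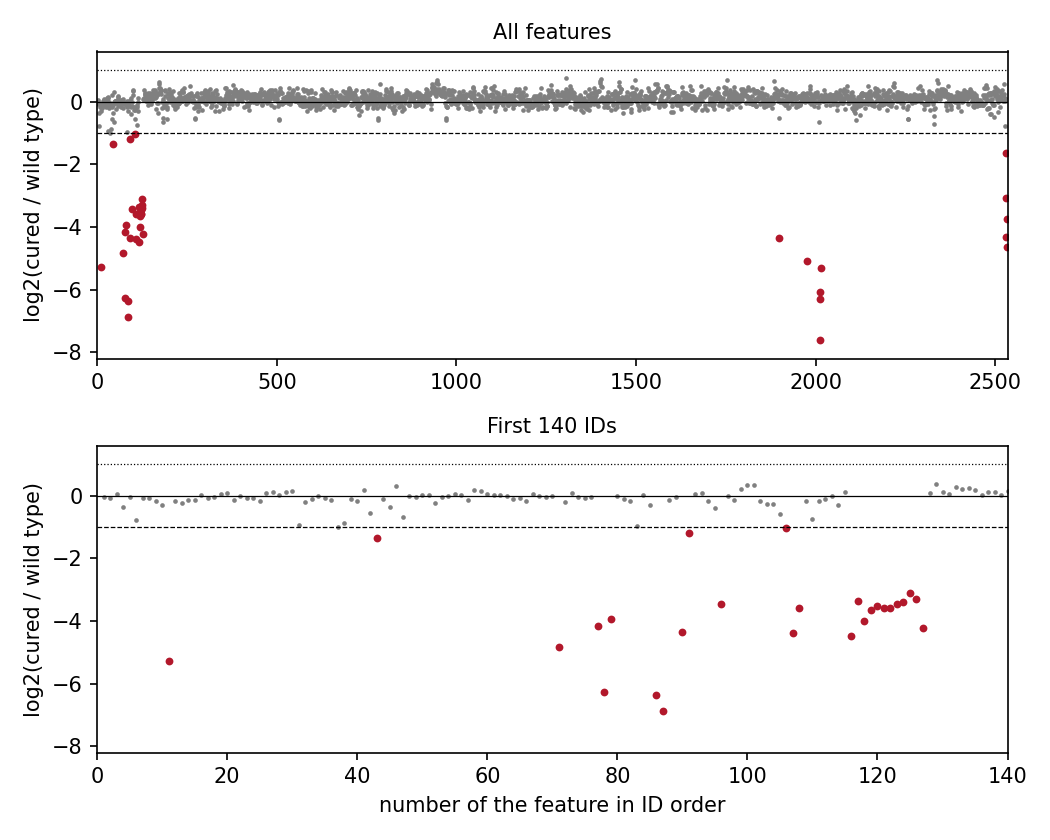
Log2 ratio of the cured variant over the wild type (vertical axis) for each feature in ID order (horizontal axis), for all 2533 features (top) and for the first IDs (bottom). Red points are the 37 features at least 2-fold lower, of which 26 fall within the first 127 IDs. Dashed and dotted lines mark 2-fold lower and 2-fold higher.

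**Figure D3:**
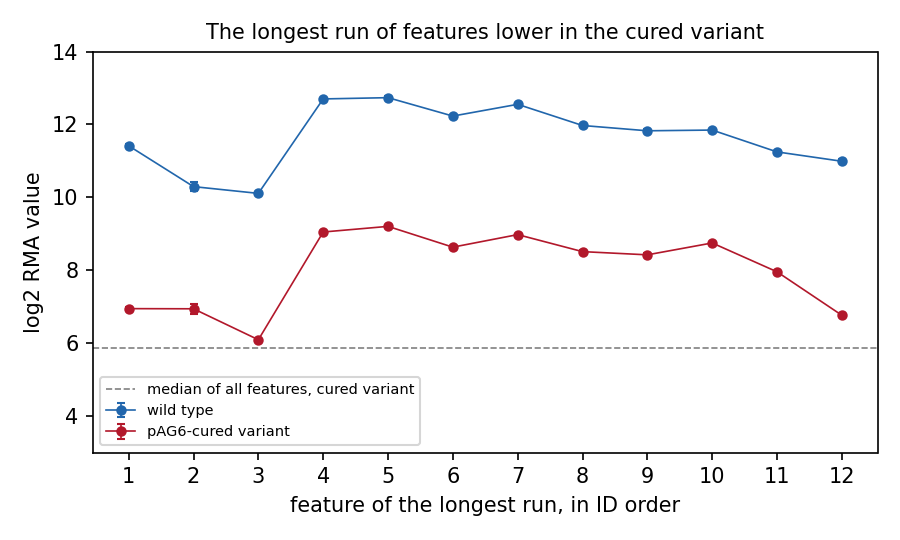
Log2 RMA value (vertical axis) of the 12 features of the longest run in ID order (horizontal axis), for the wild type (blue) and the cured variant (red), 1 array each, with the SE over probes as error bars. Every feature of the run was at least 8.55-fold lower in the cured variant, and its median of 8.47 lies above the dashed line, the array median of 5.88.

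The other 2496 features differed little between the 2 arrays. Across features the 2 arrays had a Pearson correlation of 0.978, which was 0.998 without the 37 lower ones. Those were the features that differed most, so leaving them out raises the coefficient by construction. Features are not independent replicates, and the coefficients describe these 2 arrays. The median log2 ratio over all features was 0.09, with a bootstrap interval from 0.080 to 0.098, and the quartiles were -0.03 and 0.21. The interval covers the choice of features alone, and the median depended on the scaling, with 0.054 after a second quantile normalization and 0.0011 after removal of the trend with level. A further 12 features were between 1.5-fold and 2-fold lower, most of them among the first 127 IDs, and 15 were at least 1.5-fold higher. The small upward shift depended on level. When the 2496 features were split into 8 equal parts by mean level, the median log2 ratio was -0.01 in the dimmest part, 0.23 in the seventh, and 0.09 in the brightest. Differences of this size between single arrays cannot be separated from variation between cultures or arrays, or from an effect of the normalization.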

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

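The count of 37 features at least 2-fold lower became 38 with the medians set equal, 36 after a second quantile normalization, 42 after removal of the loess curve, and 49 and 34 at thresholds of 1.5-fold and 3-fold. Of the 37, 36 were shared with the quantile setting and 37 with every other scaling, filter and pseudocount setting. The count at 8-fold, chosen after seeing the data, was 33 in each setting except the pseudocount, which gave 32. The count of features at least 2-fold higher was 0 under every setting of the values and at 3-fold, and 15 at 1.5-fold. The number of runs was 5, or 4 after quantile normalization, 7 for runs of 2 or more, and 3 for runs of 4 or more, where the minimum length itself removes those of 3 features. The median log2 ratio of 0.09 was 0.068 with medians set equal, 0.054 after quantile normalization, 0.0011 after loess, 0.13 with the level filter and 0.063 with the pseudocount. The highest log2 ratio as deposited, 0.75, ranged down to 0.52 and the second, 0.72, between 0.59 and 0.76. The 12 lowest features kept log2 ratios between -7.81 and -4.20 over the 6 settings of the values. The gene list alternatives were not run for want of gene names, and the median over repeated rows was not run because no ID was repeated. No paired analysis was possible because each strain has 1 array, and no replicate could be left out. The low end of the scale limits the folds: a value near 3 or 4 in the cured variant may be background, so that the largest folds are bounded by the level in the wild type; the lowest log2 ratio was -7.61 as deposited and -7.81 at its most negative under the alternatives.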

Other observations

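The 3 other scalings used in this part were fixed before the data were examined, and the remaining tests were chosen after the values were seen. Among the 2496 features that were not 2-fold changed, features next to each other in ID order had similar ratios. Over 2483 adjacent pairs the correlation of their log2 ratios was 0.34, against at most 0.059 in 1000 shuffles, and it was 0.26 after the trend with level was removed. Among the first 127 IDs, where most of the lower features lay, 65 of the 101 features that were not 2-fold lower were at or below the 25th percentile of the wild-type array, against 25.3 expected from the whole array. The lower features left out of the 101 were all above the wild-type median. The expected value does not allow for their removal, so the comparison overstates the excess. The longest stretch at least 1.5-fold higher in the cured variant held 3 consecutive features, with log2 ratios from 0.60 to 0.70. Genes in a bacterial operon are transcribed together. Whether these stretches are operons was not tested, and none has a replicate.

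The first pattern is the number of features that were lower. At least 36 features remained 2-fold lower under 3 other scalings, so the number hardly depended on the choice among these. All 3 acted on values already normalized by RMA and could move such large ratios little. They therefore cannot decide on the RMA normalization itself. Loss of the 8.7 kb plasmid alone cannot be told apart from loss or reduction of further sequence. Shared among the 33 features at least 8-fold lower, the plasmid would leave 264 bp for each. Feature lengths, positions and repeated or split genes on the array are unknown here, so this figure cannot decide the question. It is no evidence that the plasmid could hold all 33 features. An effect of the lost plasmid on genes located elsewhere also stays open, as untested.

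The second pattern is the signal left in the cured variant over the longest run of 12 features, where a mean of 8.04% of the wild-type value remained. An array floor is argued against for this run, whose 12 cured values all lay above the array median of 5.88, the lowest at 6.09. A floor would also make the log2 ratio fall by about 1 for each unit of wild-type level. The slope was 0.12 ± 0.13 (jackknife SE), between 0.066 and 0.23 with any 1 feature left out. The jackknife treats neighbouring features of 1 pair of arrays as independent. Over the other 21 features at least 8-fold lower the slope was -0.52 ± 0.21, which does not settle the question for them. Binding of the probes to a diverged related sequence stays open. The median probe-level SE of the run was 1.13 times that of features of similar level, at percentile 92.1 of 10000 matched lists. For the other 21 features it was 2.94 times that of features of similar level, at percentile 100 of matched lists. Features at least 8-fold lower have very different levels in the strains, so a matched level need not suit either strain. Whether this raised the SE relative to the matched lists was not tested. The deposited SE is shared by the arrays, so it cannot show in which strain the probes disagreed. The contrast therefore does not decide on diverged binding. Whether the segment was lost or only reduced was not tested, and no biological explanation was tested.

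The third pattern is a set of adjacent pairs of features modestly lower in the cured variant, at several places in the ID order. Of 32 features with log2 ratios between -1 and -0.4, 16 stood in 8 adjacent pairs, against 0.387 pairs on average and at most 4 in 1000 shuffles. In 7 of the pairs all 14 features had wild-type values between 9.76 and 10.32 and a mean log2 ratio of -0.56 with an SD of 0.067, or 32.4% lower. All 7 adjoined at least 1 further pair whose wild-type values lay between 11.80 and 12.06. These were 9 flanking pairs. They were among 12 adjacent pairs of the whole array in a window slightly wider than that range, set after the values were seen. Selection by the windows of wild-type level alone, without the ratios, gave 7 pairs next to a flanking pair, the same 7. The windows were set after the levels of these pairs were seen, so recovering the same 7 is not a check independent of the ratios. The 18 flanking features had a mean log2 ratio of -0.13 with an SD of 0.067, higher than the pairs by 0.43. These ratios were not adjusted for the trend with level. Among features not 2-fold changed, the median was 0.23 in the seventh part by level, which holds the pairs. It was 0.09 in the brightest part, which holds the flanking features, and the gap of 0.43 takes no account of this. This gap cannot decide whether copies were lost equally across the pairs and the flanking features. The pairs were first found by their low ratios, and RNA levels do not measure the number of copies. Features that share probes would also not be separate measurements. Whether these features are copies of 1 repeated sequence read by the same probes stays open, because the alike levels prompted the idea and the sequences of the features are not used here.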
